A study of Mus musculus with 24 samples.

How the data were processed

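Total RNA from striatum and cerebellum of huntingtin knock-in and wild-type mice was hybridised to Affymetrix mouse oligonucleotide arrays, 24 in all. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a Qiagen column and labelled with biotin. The labels place each array in 1 of 4 groups by genotype and tissue, 6 arrays per group, with replicate numbers 1 to 6 in each. The authors deposited 1 table of GCRMA values, per the submitters' processing notes, with the GCRMA version not given in the sources used here. GCRMA subtracts background with a model of probe sequence, makes the arrays share 1 distribution and sums the probes of a probe set into a single value. The log base is not stated. The deposited values ran from -0.77 to 16.33, a range that fits a log2 scale, and they were read as log2 values throughout. Array medians lay between 3.38 and 3.51. Whether all arrays were normalised together is not given in the sources used here.

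Within each tissue the means of replicate numbers 1 to 3 and of numbers 4 to 6 lay closer together over probe sets than those of any other equal split of the arrays. The SD over probe sets of the difference between these means was 0.0392 in striatum and 0.0384 in cerebellum, and the lowest SD among the other ways to split the 12 arrays of a tissue equally was 0.0769 and 0.0723. No label records a step that sets these means equal. If there was such a step, the model without the number set counts 1 degree of freedom per tissue too many, so values with the number set in the model, and within each set, are given beside the counts.

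The table held 45101 probe sets, of which 64 were controls and were left out. A probe set was kept if its mean was at least 4 in striatum or in cerebellum, which left 20738, or 46.0% of the 45037 others. Of these 45037, 34945 pair with 1 gene symbol in the platform annotation of 2016, 932 with several and 9160 with none. Entrez identifiers matched 34741 of the single-symbol probe sets to the GRCm38.p6 gene table, which changed 0 symbols and was used only for names, chromosomes and neighbouring genes, since the files name no genome build. No coordinates are given.

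All 24 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 with 20 residual degrees of freedom and a prior of 3.22. Every adjusted p of a gene is limma's moderated test with Benjamini-Hochberg adjustment over the kept probe sets, and the threshold was an adjusted p of 0.05. The comparisons were Q111 against wild type in each tissue, the difference between these differences (the interaction), and striatum against cerebellum in wild type. For a gene with several probe sets, the one with the highest mean over all arrays stood for it, giving 10766 genes. Named genes were taken by a rule fixed before the data were examined: the 12 largest rises and 12 largest falls past the threshold in each genotype comparison and the interaction, 8 each way between the tissues, up to 3 members past the threshold from each gene list or otherwise up to 2 given as values, and Htt.

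In the same way, 38 gene lists of cell types and pathways were fixed. Each was tested with camera in limma at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry; adjusted p covers the 38 lists of a comparison. A list's score is the mean log2 value of its genes on an array, and scores were compared between genotypes with a two-sided exact permutation test over the 6 and 6 arrays. The alternatives covered the filter, further quantile normalisation or median centring, the variance prior, array weights, the replicate number or number set in the model, each tissue or number set alone, thresholds, and leaving out each array. Covariates for Xist and for the scores of cortex, thalamus and choroid plexus genes, the product of genotype and number set, a fit without arrays standing apart, and bounds with values under 4 set to 4 were added after seeing the data.

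The model was tested on simulated arrays with the spread of the real ones, in which 200 of the 20738 probe sets were changed. In striatum it called 32% of those changed 1.25-fold, 52% at 1.5-fold, 94% at 2-fold and 98% at 3-fold, with 9.21% of its calls false. In cerebellum the shares were 22%, 76%, 100% and 98%, with 3.9% false, and for the interaction 14%, 40%, 70% and 98%, with 5.13% false. Between tissues they were 38%, 72%, 100% and 100%, with 3.73% false. In simulated lists of 25 independent genes, camera called 20 of 20 that were shifted by 0.4 and 0 of 380 that were not. Real genes are correlated, and among other splits of the real arrays camera called a median of 5 of the 38 lists in striatum and 3 in cerebellum. The number of arrays limits the precision.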

Results

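Messenger RNA was measured in the striatum and cerebellum of mice homozygous for a huntingtin knock-in allele with an expanded glutamine stretch, named Q111 for its length, and of mice homozygous for the wild-type allele. Huntingtin (Htt, formerly Hdh) carries the CAG repeat whose expansion causes Huntington's disease, in which striatal projection neurons are the cells most affected and the cerebellum is less so. Each of the 4 combinations of genotype and tissue had 6 arrays. The labels give age only as a range of 3 to 10 weeks, and they do not give sex or say whether both tissues came from the same mice. They call the replicates biological without naming separate mice, so p-values measure the spread between these samples, which may be partly technical. Across probe sets, arrays of a group correlated at 0.994 to 0.998 and arrays of different tissues at 0.932 to 0.950, and no pair of arrays held identical values.

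Htt itself was measured by 4 probe sets, of which 3 passed the filter. The brightest read 7.83 ± 0.13 log2 in Q111 striatum and 7.83 ± 0.15 in wild type (SD, n = 6 arrays each; exact permutation p = 0.961). In cerebellum it read 7.68 ± 0.16 in Q111 and 7.95 ± 0.16 in wild type, a difference of -0.27 (SE 0.09) seen in 5 of 6 Q111 arrays. That difference had an exact permutation p of 0.026 and missed the threshold across all probe sets (adjusted p = 0.178). These probe sets were not placed relative to the repeat here, so they do not check the genotype. Of 31 measured genes near Htt on chromosome 5, limma called 0 in either tissue (adjusted over the list alone, 1 was higher in striatum and 1 lower in cerebellum), against 3933 probe sets in striatum and 2867 in cerebellum at an unadjusted p under 0.05. The 31 had a median log2 difference of 0.00 in striatum and 0.04 in cerebellum; their largest difference was that of Rgs12, a regulator of G protein signalling, at 0.71 in striatum (adjusted p = 0.0511, higher in 5 of 6 arrays).

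The genotype comparison in striatum asks what the expanded allele changes in the most affected tissue. Nudt19, which encodes a coenzyme A hydrolase, fell by 1.71 log2 (SE 0.12), from 8.60 ± 0.11 in wild type to 6.89 ± 0.12 in Q111 (SD, n = 6; adjusted p = 2.47e-08). Npas2, a transcription factor of the circadian clock, rose by 1.24 (SE 0.18, adjusted p = 5.73e-04), and Nr2e1, a nuclear receptor of neural stem cells, fell by 0.99 (SE 0.10, adjusted p = 6.13e-06). Neurod6 and Fezf2, transcription factors of cortical projection neurons, rose by 1.12 (SE 0.20) and 0.71 (SE 0.15). The complement genes C1qa, C1qb and C1qc, made in brain mainly by microglia, rose by 0.44 (SE 0.12), 0.67 (SE 0.12) and 1.04 (SE 0.25). For these and the genes below, all 6 Q111 arrays lay beyond the wild-type mean, except 5 of 6 for Neurod6 and Ifit2.

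Other large rises in striatum were those of Gm1976 (1.68), the kinase gene Mapk8 (1.28), the interferon-induced Ifit2 (1.10), Srd5a3, a reductase of polyprenol (1.10), Tmem242 (0.97), Polr1c, a subunit of RNA polymerases (0.89), the potassium channel Kcna5 (0.81), Marf1 (0.80) and Crh, which encodes corticotropin-releasing hormone (0.80). Their adjusted p ranged from 7.86e-04 for Srd5a3 to 0.0448 for Polr1c. The largest falls after Nudt19 were those of Dmkn, the gene of a secreted epithelial protein (log2 change -1.51, adjusted p = 2.11e-04), Gprin3 (-1.16), the phosphoinositide phosphatase Mtm1 (-1.10), and Sbsn, which encodes suprabasin (-1.09). They were followed by the transcription factor Ets1 (-1.05), the cofilin phosphatase Ssh1 (-1.03), Plxdc1 (-0.94), Fam184b (-0.89), Mpp7 (-0.88) and the protease Klk6 (-0.86). At least 1 other probe set past the filter had the opposite sign for Mapk8, Srd5a3, Polr1c, Marf1, Mtm1, Fam184b and Mpp7. Ifit2 averaged under 4, near background, in wild type and Mpp7 in Q111, so with values under 4 set to 4 their changes are at least 0.64 and -0.65.

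Medians of the cell type lists in striatum lay on both sides of 0, and no list passed camera with an estimated correlation. Of 12 cerebral cortex neuron genes, Neurod6 and Fezf2 rose (5 rose adjusted over the list alone), 11 were higher, and the median was 0.39 (camera adjusted p = 1.23e-05, adjusted p = 0.199 with an estimated correlation). The cortex score was 8.39 ± 0.26 in Q111 and 7.999 ± 0.22 in wild type (SD, n = 6; exact permutation p = 0.0238, adjusted 0.197 over the lists). It was higher in 5 of 6 arrays, by 0.53 in numbers 1 to 3 and 0.26 in numbers 4 to 6. Of 35 striatal projection neuron genes 1 fell, the receptor Gpr149 (-0.38, adjusted p = 0.0467; 1 fell adjusted over the list alone), and 6 were higher. The median was -0.22 and the list missed the threshold (camera adjusted p = 0.0515). Its score differed by -0.49 in numbers 1 to 3 and by 0.13 in numbers 4 to 6, so the sign did not repeat. Among its best-known members, chosen after their values were seen, Penk, which encodes proenkephalin, had a log2 difference of -0.34 (adjusted p = 0.0962). The dopamine receptor genes Drd2 and Drd1 had -0.25 (adjusted p = 0.476) and 0.01 (adjusted p = 0.989), and Tac1 -0.05 (adjusted p = 0.930).

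Of 21 myelinating oligodendrocyte genes, limma called 0 (3 fell adjusted over the list alone), 2 were higher and the median was -0.20, with Opalin at -0.48 and Aspa at -0.45 (camera adjusted p = 0.0196, adjusted p = 0.859 with an estimated correlation). Of 13 endothelial and mural cell genes 2 fell (4 adjusted over the list alone), the tight junction gene Cldn5 (-0.73, adjusted p = 5.99e-04) and the pericyte gene Rgs5 (-0.30, adjusted p = 0.0407, with another probe set of opposite sign). That list's median was -0.13 and it missed the threshold with camera (adjusted p = 0.0685, adjusted p = 0.707 with an estimated correlation) and passed with fry (adjusted p = 0.0219), which also called the cortex neuron list (adjusted p = 0.0216). Of 16 microglia genes the 3 complement genes rose and Aif1, named after its value was seen, fell (-0.34, adjusted p = 0.0499), the same counts as adjusted over the list alone. The median was 0.00 and the mean 0.11 (camera adjusted p = 0.107). Single members of other lists that passed were Slc7a10 of astrocytes (-0.43), Lhx2 (0.44), listed for thalamus and septum, Ptgds of the meninges (0.59) and Pcp4 (-0.22), listed for Purkinje cells. Lhx2 was higher in numbers 1 to 3 and 4 to 6 alike (0.33 and 0.55), while the score of its list changed sign between them (0.95 and -0.72).

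Among pathways, 5 of 70 oxidative phosphorylation genes fell in striatum (12 fell and 1 rose adjusted over the list alone). They were Atp5g1 (-0.34) and Atp5g2 (-0.27), which encode subunit c of ATP synthase, Cox5b of cytochrome oxidase (-0.30), and Ndufs3 (-0.18) and Ndufs4 (-0.25) of complex I, both named after their values were seen. The list's median was -0.09 (camera adjusted p = 5.27e-04, adjusted p = 0.859 with an estimated correlation), and its score differed by -0.03 in numbers 1 to 3 and -0.15 in numbers 4 to 6. Quantile normalisation moved that median to -0.06 and median centring to -0.04, and the list stayed past the threshold with camera under both. Of 22 endoplasmic reticulum stress genes 1 rose, the chaperone gene Hsp90b1 (0.31, adjusted p = 0.0266; 3 rose adjusted over the list alone), and 19 were higher, with a median of 0.09 (camera adjusted p = 0.00101, adjusted p = 0.707 with an estimated correlation). The score of that list differed by 0.26 in numbers 1 to 3 and by -0.01 in numbers 4 to 6. Of 21 neuronal targets of the repressor REST, 0 passed in limma (2 rose adjusted over the list alone) and 14 were higher, including Stx1a at 0.62 (adjusted p = 0.0755). Their median was 0.08 (camera adjusted p = 0.0130, adjusted p = 0.707 with an estimated correlation). Of 24 cholesterol biosynthesis genes 0 passed (2 fell adjusted over the list alone) and 3 were higher, with a median of -0.16 and Dhcr7 at -0.40 (camera adjusted p = 0.0262, adjusted p = 0.847 with an estimated correlation). Single members of further lists that passed were the immediate early gene Jun (0.51), the adenylyl cyclase gene Adcy1 (0.43), the GABA receptor subunit gene Gabra5 (0.56), the repair nuclease gene Fen1 (0.27), and the purine enzymes Adssl1 (-0.64) and Pnp (-0.38).

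In total 595 of 20738 probe sets were called in striatum, 173 up and 422 down, of which 181 changed at least 1.5-fold and 38 at least 2-fold; they represent 94 genes up and 205 down. The share of falls, 70.9%, depended on scaling: quantile normalisation gave 305 up and 330 down (52.0% down) and median centring 331 up and 247 down (42.7% down). It also differed between the number sets, with 75 up and 167 down (69.0% down) in numbers 1 to 3 alone and 157 up and 94 down (37.5% down) in numbers 4 to 6 alone. With the number set in the model 316 were called, all among the 595, and within numbers 1 to 3 and 4 to 6 alone 242 and 251 were called, of which 56 and 57 were among the 595. With the cortex score as a covariate, added after seeing the data, 27 were called, and without a filter 384. Leaving out 1 array moved the count by over 1.5 times for wild-type arrays 3 (354), 4 (219) and 6 (372) and Q111 arrays 1 (325), 2 (385), 5 (352) and 6 (272). Across all probe sets, the differences of the 2 number sets correlated at -0.0841, with 50.1% of the same sign. Of 100 splits of the 12 arrays, 44 called as many lists as the real one's 6.

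**Figure D1:**
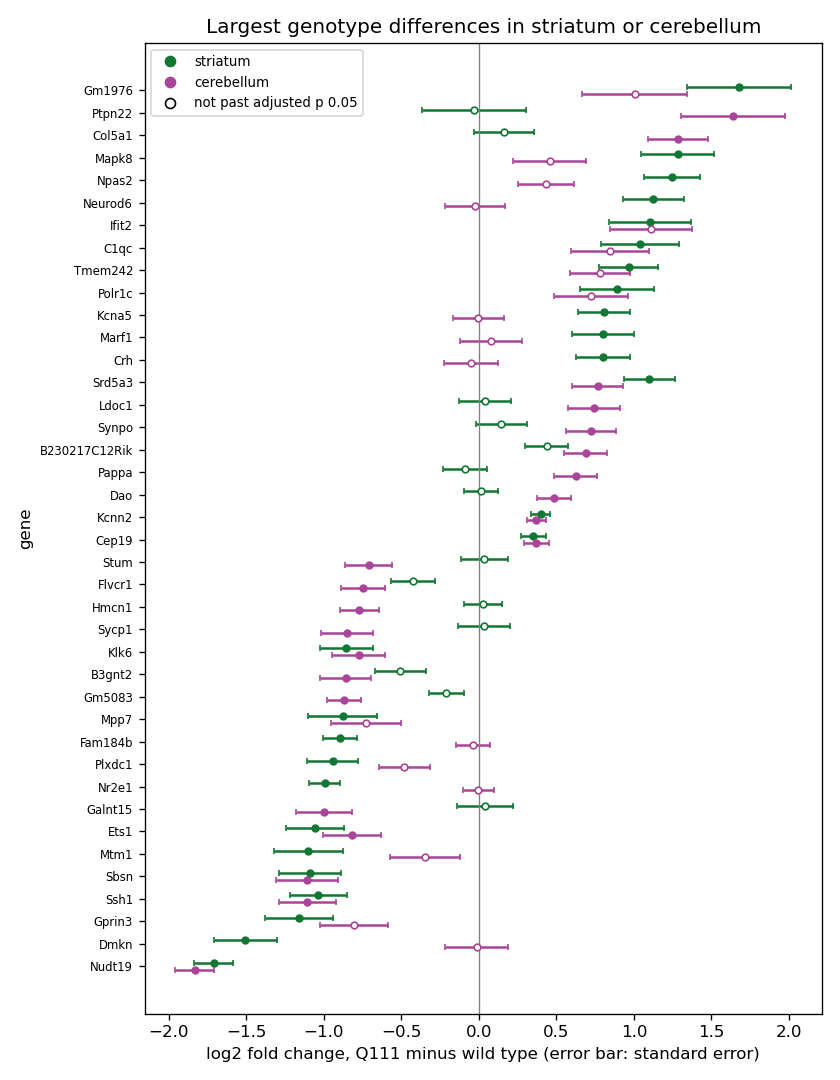
Log2 fold change of Q111 against wild type (horizontal axis, ± SE) for 40 named genes in striatum (green) and cerebellum (purple), 6 arrays per group, with open points for genes that missed an adjusted p of 0.05. Nudt19 lies at -1.71 in striatum and -1.83 in cerebellum, and Nr2e1 at -0.99 in striatum, where its interaction with tissue is also -0.99.

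**Figure D2:**
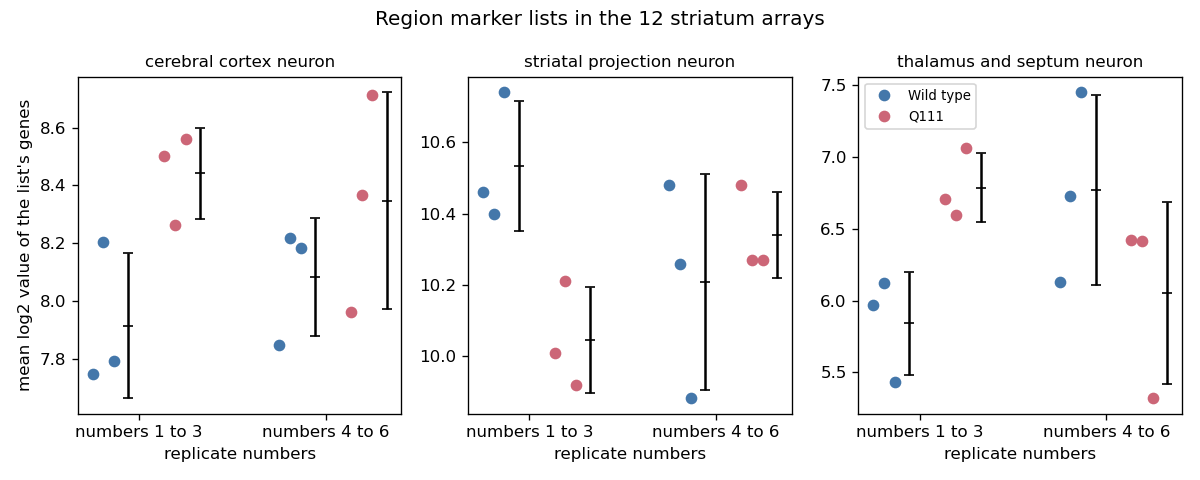
Mean log2 value per striatum array of the cortex neuron, projection neuron and thalamus gene lists, by genotype and replicate number set; points are arrays and bars are the mean ± SD of 3 arrays. Cortex scores are higher in Q111 in both sets (by 0.53 and 0.26), while projection neuron scores differ by -0.49 and 0.13 and thalamus scores by 0.95 and -0.72.

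In cerebellum, the less affected tissue, Nudt19 again had the largest fall, by 1.83 log2 (SE 0.12, adjusted p = 5.89e-09). Ptpn22, a tyrosine phosphatase gene of lymphocytes, rose by 1.64 (SE 0.34, adjusted p = 0.0252), and Col5a1, a fibrillar collagen gene, rose by 1.28 (SE 0.19, adjusted p = 0.00149). Ssh1 (-1.11, SE 0.18), Sbsn (-1.11, SE 0.20), the glycosyltransferase gene Galnt15 (-0.996, SE 0.18) and Hmcn1, which encodes an extracellular matrix protein (-0.77, SE 0.12), also fell. Kcnn2, a calcium-activated potassium channel gene, rose by 0.37 (SE 0.06, adjusted p = 0.00326). Further falls were those of Gm5083 (-0.87), B3gnt2 (-0.86), Sycp1 of the synaptonemal complex (-0.85), Ets1 (-0.82), Klk6 (-0.78), the heme exporter gene Flvcr1 (-0.75) and Stum (-0.71). Further rises were those of Srd5a3 (0.77), Ldoc1 (0.74), Synpo, which encodes the actin-binding protein synaptopodin (0.72), B230217C12Rik (0.69), the protease gene Pappa (0.62), Dao, which encodes D-amino acid oxidase (0.49), and Cep19 (0.37). All 6 Q111 arrays lay beyond the wild-type mean for each, except 5 of 6 for Dao. Of these 22 genes, 8 stayed past the threshold whichever array was left out. Synpo averaged under 4 in wild type, so its rise is at least 0.26 with values under 4 set to 4.

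Of 24 cholesterol biosynthesis genes in cerebellum, limma called 0 over all probe sets and 9 fell adjusted over the list alone; 1 was higher and the median was -0.20, with Dhcr7 at -0.55 (adjusted p = 0.0987) and Cyp51 at -0.44 (adjusted p = 0.0908). The camera adjusted p was 1.92e-04, with adjusted p = 0.484 with an estimated correlation and a fry adjusted p of 0.0250. Its score was 8.18 ± 0.06 in Q111 and 8.38 ± 0.09 in wild type (SD, n = 6), lower in all 6 Q111 arrays (exact permutation p = 0.00217, adjusted 0.0823 over the lists). It differed by -0.27 in numbers 1 to 3 and -0.13 in numbers 4 to 6. Quantile normalisation moved the median to -0.14 and median centring to -0.10, and the list stayed past the threshold with camera under both. Of 16 microglia genes 0 passed (3 rose adjusted over the list alone), 11 were higher and the median was 0.06, with C1qb at 0.41 (camera adjusted p = 0.00458, adjusted p = 0.484 with an estimated correlation). In 5 of these 16 a group averaged under 4, among them C1qc, higher by at least 0.39, and with values under 4 set to 4 the median was 0.01. Of 20 granule neuron genes 0 passed, and 0 did so adjusted over the list alone; 14 were higher and the median was 0.05 (camera adjusted p = 0.0186, adjusted p = 0.654 with an estimated correlation). Quantile normalisation and median centring ended the call of the granule neuron list (camera adjusted p = 0.187 and 0.141), and median centring that of the microglia list (camera adjusted p = 0.0821). Of 17 immediate early genes 0 passed (3 fell adjusted over the list alone) and 3 were higher, with Nr4a2 at -1.41 (adjusted p = 0.05002) and Fos at -1.02 (adjusted p = 0.265). The median was -0.34 and the list missed the threshold (camera adjusted p = 0.0762). At an unadjusted p under 0.05, limma gave 2867 probe sets in this tissue.

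In total 95 probe sets were called in cerebellum, 20 up and 75 down, of which 53 changed at least 1.5-fold and 14 at least 2-fold; they represent 10 genes up and 38 down. The share of falls, 78.9%, again depended on scaling: quantile normalisation gave 50 up and 40 down (44.4% down) and median centring 90 up and 35 down (28% down). It was 90.9% in numbers 1 to 3 alone (1 up and 10 down) and 83.3% in numbers 4 to 6 alone (3 up and 15 down). With the number set in the model 49 were called, all among the 95, and within numbers 1 to 3 and 4 to 6 alone 11 and 18 were called, of which 6 and 6 were among the 95. With array weights 396 were called, 80 up and 316 down, all 95 among them. Leaving out 1 array moved the count by over 1.5 times for wild-type arrays 1 (39), 2 (194) and 6 (56) and Q111 arrays 3 (34), 5 (39) and 6 (252). It moved the list count of 3 by over 1.5 times for wild-type array 3 (5) and Q111 arrays 3 (6) and 5 (6). Across all probe sets the differences of the number sets correlated at 0.147, with 57.0% of the same sign. Of 100 splits of the 12 arrays, 57 called as many lists as the real one's 3.

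The tissues shared 16 called genes, all with the same direction. Cep19 (0.35 in striatum, 0.37 in cerebellum), Srd5a3 (1.10, 0.77) and Kcnn2 (0.40, 0.37) rose in both. Nudt19 (-1.71, -1.83), Sbsn (-1.09, -1.11), Ets1 (-1.05, -0.82), Ssh1 (-1.03, -1.11), Klk6 (-0.86, -0.78), and the clock gene Per3 (-0.60, -0.62) fell in both. So did Phtf1 (-0.60, -0.58), the non-coding RNA genes Gas5 (-0.56, -0.60) and Snhg6 (-0.30, -0.25), Atraid (-0.44, -0.36), the transcription factor gene Jund (-0.39, -0.48), Pag1 (-0.35, -0.32) and Abhd11 (-0.32, -0.29). Those of the 16 outside the naming rule are given because they complete the set, after their values were seen. Independent lists of these sizes among 10766 genes would share 0.0873 rises and 0.724 falls, and 0 genes were called in opposite directions, where 0.332 and 0.190 would be expected. Of the 48 genes called in cerebellum 38 (79.2%) had the same sign in striatum, and across all genes the differences correlated at r = 0.275 (rho = 0.216, covariance 0.00856); genes are not independent replicates.

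The genotype difference itself was compared between tissues by the interaction, which called 9 genes. Dmkn fell in striatum by 1.51 and differed by -0.01 in cerebellum (interaction -1.49, SE 0.29, adjusted p = 0.0458). Nr2e1 (-0.99, SE 0.14, adjusted p = 0.00737) and Fam184b (-0.86, SE 0.16, adjusted p = 0.0369) likewise fell in striatum relative to cerebellum. In cerebellum Dmkn, Nr2e1 and Fam184b averaged 1.42, 2.76 and 2.21 in wild type, near background, where a fall would not be seen. Lower in striatum relative to cerebellum were also Tinf2 of the telomere complex (-0.63, SE 0.12, adjusted p = 0.0424) and Tmem41a (-0.41, SE 0.08, adjusted p = 0.0478). Jun (0.88, SE 0.14, adjusted p = 0.00975) and Lrp4, a receptor of the synapse (0.72, SE 0.11, adjusted p = 0.00975), had a more positive difference in striatum. The calcium sensor gene Cabp1 (1.22, SE 0.24, adjusted p = 0.0478) and Numbl, a homologue of the fate regulator Numb (0.57, SE 0.11, adjusted p = 0.0490), did so too. In striatum all 6 Q111 arrays lay beyond the wild-type mean for each of the 9. Cabp1 was the single member not called in either tissue, at 0.60 in striatum and -0.62 in cerebellum. All 12 cortex neuron genes had a positive interaction, with a median of 0.37 (2 rose adjusted over the list alone; camera adjusted p = 0.00153, adjusted p = 0.777 with an estimated correlation). The oxidative phosphorylation list had a median interaction of -0.06, with 0 of 70 genes called and 0 adjusted over the list alone (camera adjusted p = 0.00227, adjusted p = 0.817 with an estimated correlation). The projection neuron list had a median of -0.08, with 0 of 35 called and 3 lower adjusted over the list alone (camera adjusted p = 0.00696, adjusted p = 0.817 with an estimated correlation).

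In total the interaction called 18 probe sets, 9 each way, of which 15 differed at least 1.5-fold, with 2100 at an unadjusted p under 0.05. With the number set in the model 6 were called, with the cortex score as a covariate 2, with array weights 64, and with a filter of 6 in place of 4 there were 7. With the replicate number as a block 1 was called, and all 9 genes above missed the threshold. Within numbers 1 to 3 and 4 to 6 alone, 10 and 30 were called, of which 2 and 1 were among the 18. Leaving out 1 array gave over 1.5 times more calls without wild-type striatum arrays 1 (50) and 5 (28), Q111 striatum arrays 2 (30) and 4 (30), wild-type cerebellum array 2 (40) and Q111 cerebellum array 6 (36). It gave fewer by that factor without wild-type striatum arrays 3 (8) and 4 (9) and Q111 striatum arrays 1 (6), 3 (11), 5 (7) and 6 (10). The same held without wild-type cerebellum arrays 1 (8), 3 (6), 4 (10) and 6 (8) and Q111 cerebellum arrays 1 (10), 2 (6), 3 (6) and 5 (7).

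Striatum and cerebellum of wild-type mice differed in the genes that mark their neurons. Gabra6 and Cbln3, genes of cerebellar granule neurons, averaged 13.78 and 13.63 log2 in cerebellum and under 4, near background, in striatum. With values under 4 set to 4, their log2 differences in striatum were -9.78 and -9.63, and that of the Purkinje cell gene Pcp2 -10.47, each a lower bound on the size of the difference. Ddn, a postsynaptic gene of forebrain neurons, was higher in striatum by at least 8.19 and the dopamine receptor gene Drd2 by at least 7.48, and Tac1, the gene of substance P, measured in both tissues, by 9.30 (SE 0.22), each with an adjusted p of 2.74e-21 or less. Further genes higher in striatum, each by at least the value given, were Nrgn (8.35), Gpr6 (7.38), Egr3 (7.15), Ptk2b (6.73) and Ankrd63 (6.09). Lower by at least the value given were Cbln1 (-9.89), Cnpy1 (-8.09) and Ppp1r17 (-7.21), and Neurod1 (-9.99) and Calb2 (-7.89) were lower and measured in both tissues. These bounds have no order among them. All 6 striatum arrays lay beyond the cerebellar mean for each.

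Of 35 striatal projection neuron genes 32 were higher in striatum and 1, the transcription factor gene Ebf1, was lower (-2.12), with a median of 5.25 (5.12 with values under 4 set to 4). All 20 granule neuron genes were lower (median -4.26, or -3.95 with that floor), as were 15 of 19 Purkinje cell genes, while Pcp4 (0.62), Foxp2 (4.19) and Stmn4 (1.39) of that list were higher. Of 10 Bergmann glia genes 9 were lower, among them A2m (-4.55) and Hopx (-4.16), and Gria1 was not called; of 9 meningeal genes 8 were lower, among them Fmod (-3.445 with that floor). Members of these lists outside the naming rule, Ebf1, Pcp4, Foxp2, Stmn4 and Gria1, were named after their values were seen. All 16 microglia genes were higher in striatum (median 1.93, or 1.73 with that floor), with P2ry12 at 3.02 and Csf1r at 2.50, and of 42 genes of cAMP, dopamine and G protein signalling 30 were higher and 9 lower, with Pde1b at 8.54. The adjusted p of these lists with an estimated correlation was 0.0329 for projection neurons, Purkinje cells and Bergmann glia, 0.025 for meninges and 0.00697 for granule neurons, microglia and cAMP signalling. The counts adjusted over the list alone were equal to these. Of 21 oligodendrocyte genes 19 were higher and 1 lower, and of 70 oxidative phosphorylation genes 53 were lower, both also adjusted over the list alone, with adjusted p = 0.241 and adjusted p = 0.595 with an estimated correlation. In total 14890 probe sets were called, 6342 higher and 8548 lower in striatum, representing 3459 and 4481 genes.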

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

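The tests of the cortex score as a covariate, of cell types raised alike, of cortex against projection neuron scores, of linkage to Htt, of shared mice and of the split crossed with the number sets were chosen after the result was seen. Those of exchanged labels, of composition between number sets, of the time of day and of drawn splits of the arrays were set out beforehand.

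Nr2e1 fell in striatum, with a tissue difference of -0.99 that stayed past the threshold whichever array was left out, as did those of Jun (0.88) and Lrp4 (0.717). The other tissue differences that passed the interaction test were Dmkn (-1.49), Cabp1 (1.22), Fam184b (-0.856), Tinf2 (-0.631), Numbl (0.572) and Tmem41a (-0.41). In cerebellum Nr2e1, Dmkn and Fam184b averaged 2.76, 1.42 and 2.21 in wild type, near background, where a fall would not be seen, so these 3 do not show that the allele acts differently there. None of these 9 passed under every other setting.

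In 9 of 222 groups of 6 arrays, an array's gap to its nearest neighbour took a larger share of the group's range than Dixon's 95% critical value, where chance alone gives 11.1 such groups. In Q111 striatum these were Dmkn (share 0.632, replicate 4 at 6.34 log2 and its neighbour at 5.27), Neurod6 (0.689, replicate 4 at 5.76 and 6.91) and Srd5a3 (0.7, replicate 5 at 5.78 and 6.56). In wild-type striatum they were Marf1 (0.654, replicate 1 at 9.46 and 8.64), Numbl (0.63, replicate 1 at 7.60 and 7.34) and Drd2 (0.682, replicate 6 at 10.7 and 11.5). In cerebellum they were Dao (0.856, Q111 replicate 1 at 8.37 and 8.93), Tinf2 (0.73, Q111 replicate 1 at 7.88 and 8.10) and Gabra6 (0.657, wild-type replicate 2 at 13.7 and 13.8).

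For the counts of called probe sets, the real split was set against others among 100 drawn of 462, which treat single arrays as exchangeable. Of these, 1 (the real split) reached 595 calls in striatum, with 35 the highest of the others. Among the 43 others that, like the real one, took 3 arrays of each number set, the highest was 16 in striatum and 23 in cerebellum. A further split of the striatum arrays that was not among those drawn, wild type 1 to 3 with Q111 4 to 6 against the rest, called 910, so the real split is not the highest of all. The other splits drawn break up these blocks of 3 arrays. For the genotype comparisons they therefore do not exclude a chance difference between blocks. The real split was also the highest of those drawn for 95 calls in cerebellum (highest other 41), 18 for the interaction (2), 14890 between tissues (11050) and r = 0.275 between the genotype differences of the tissues (0.24). Chance cannot be excluded for the number of gene lists, since 44 of 100 splits called as many as the 6 in striatum (highest other 15) and 57 as many as the 3 in cerebellum (highest other 11).

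The calls in Q111 striatum came with higher cortex neuron genes, which more cortex tissue in those samples could bring. That list missed the threshold in camera with an estimated correlation (adjusted p = 0.199). Its score missed it in the exact permutation test (p = 0.197 adjusted over the lists). With the cortex score as a covariate, the 593 called probe sets outside that list kept a median share of 0.942 of their log2 fold change. The quartiles were 0.808 and 1.09, and all kept their sign. Of these 593, 21 stayed called, as the median SE rose from 0.103 to 0.136 and the median absolute change went from 0.447 to 0.416. The covariate's slope rests on variation within genotypes. Probe sets called for a small spread there can hardly follow the score, so the share kept does not decide on cortex tissue as their cause. Fewer projection neurons with all other cell types raised alike was not decided. The farthest of the 6 pairs of 4 cell types, cortex and oligodendrocyte scores, moved apart by 0.596 (SE 0.189, 5 of 6 arrays, n = 6). That is beyond 2 SE but short of 0.05 over the pairs (exact permutation p = 0.0108, Holm-adjusted 0.0649). The account needs all 4 scores to be higher in Q111. Microglia scores differed by 0.11 (SE 0.05), but astrocyte scores by -0.004 (SE 0.04) and oligodendrocyte scores by -0.20 (SE 0.09). More cortex tissue, which could also lower oligodendrocyte genes, stays open for the cortex list. Within genotypes its score fell as the projection neuron score rose (r = -0.647, permutation p = 0.0231, and rho = -0.622, permutation p = 0.0454). This was 1 relation tested on n = 12 arrays, with r = -0.562 without the 2 farthest arrays. Rgs4, its most abundant gene at 12.73 in wild-type striatum, differed by -0.31. In cerebellum Rgs4 also differed by -0.31, near background (3.995 in Q111, 4.31 in wild type), so this 1 gene does not decide. All 12 genes of the list averaged over 4 in wild-type striatum, and an effect of the allele on them was not tested apart from dissection.

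Genes called in the same direction in both tissues could reflect the allele, linked sequence variants or how the mice were sampled. Of the 16, 4 (Atraid, Abhd11, Srd5a3 and Ssh1) lie on chromosome 5 with Htt, where random sets averaged 1.06 and 1.76% held as many. None of the 4 was in the list of genes near Htt, and their distances from it were not used, so how closely they are linked is not given. Without sequence, a linked variant and the allele cannot be told apart for them. The 12 on other chromosomes are not linked to Htt by position, and an effect of a linked variant on them from a distance was not tested. Among them Nudt19, Sbsn and Klk6 lie on chromosome 7, Gas5 and Snhg6 on chromosome 1, and Pag1 and Phtf1 on chromosome 3. Unlinked strain differences were not tested either, so these genes cannot be credited to the allele. Same-numbered arrays of the tissues correlated at a mean of 0.0619 (SD 0.0758), and by Xist 1 same-numbered pair (Q111 number 5) was low in 1 tissue and high in the other, 5 were alike and 6 (numbers 1 to 3) had no high or low level in cerebellum, so that pair did not come from 1 mouse as labelled, which argues against 1 mouse for each pair, and the other pairs stay open. Since Per3 was lower in both tissues and Npas2 higher in striatum, a difference in the time of day at dissection was tested on 7 other clock genes: 71.4% of 14 gene and tissue pairs (10) went the way it needs, none past the threshold, which does not decide, and an effect of the allele stays open.

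Over all striatum probe sets, the genotype differences of replicate numbers 1 to 3 and 4 to 6 correlated at -0.0841, and a split that sets wild type 1 to 3 with Q111 4 to 6 against the rest called 910 probe sets. That exceeds the real 595 and points to a structure of the samples (in cerebellum that split called 0, the real one 95). The labels do not say whether the number sets differ in age or in experiment, so neither could be tested as its source. Exchanged genotype labels in 1 set would turn the signs there, but 77.1% of the genes called in cerebellum (37 of 48) had the same sign in both sets of striatum, which argues against it. The exact 95% interval of 62.7 to 88 takes genes as independent, which they are not, so it understates the uncertainty. Differing cell composition of the dissected tissue stays open. The thalamus and septum list had a median difference of 1.08 in numbers 1 to 3 and of -1.03 in numbers 4 to 6. Its median crossed difference was 2.37 log2, the farthest from 0 of the lists of other cell types. The prediction asked only that 1 of these lists pass a bound below the SD of the thalamus score between striatum arrays (0.59 in Q111, 0.70 in wild type). Chance could easily meet that bound, so the test does not decide. The variation in thalamic genes such as Slc17a6 (2.02 and -1.01) and Prkcd (1.35 and -1.09) may come from where the striatum was separated from its neighbours. With the thalamus score as a covariate, 721 probe sets were called between genotypes in striatum, a count that does not test this source of variation.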

How the results depend on the processing

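The fits with covariates, with genotype by number set, without arrays that stand apart, the interaction and tissue counts within number sets, the list counts under other scaling and the matchings within number sets were chosen after seeing the data. No named gene past the threshold and no called list's median changed sign under the settings run. Medians of lists not called changed sign with quantile normalisation or median centring for 14 lists in striatum, 21 in cerebellum and 8 for the interaction, as did the Htt difference in striatum (-0.00465 as reported, 0.0436 and 0.0451; SE 0.0883). Single genes kept their side of the threshold in 2032 comparisons and missed it in 367, and list medians in 50 and 22. The gene totals pool genotype, interaction and tissue genes. Most misses lay outside the 130 genes compared between tissues, of which at most 9 missed it in any setting. Of the named genes, 3 of 44 in striatum (Nudt19, Nr2e1 and Fam184b), 1 of 22 in cerebellum (Nudt19), 0 of 9 for the interaction and 121 of 130 between tissues passed in limma under all settings that left out no single array. In striatum and cerebellum alone these included fits on numbers 1 to 3 and 4 to 6 alone. There 32 and 33 of the 44 missed the threshold in striatum, and 20 and 20 of the 22 in cerebellum. Whichever array was left out, 28 of 44, 8 of 22, 3 of 9 and 129 of 130 passed in turn. For striatum, cerebellum and the interaction in turn, calls numbered 595, 95 and 18 as reported, 316, 49 and 6 with the number set in the model, and 304, 45 and 6 with genotype by number set. They numbered 242, 11 and 10 in numbers 1 to 3 alone, 251, 18 and 30 in numbers 4 to 6 alone (fewer samples), and 86, 28 and 4 at an adjusted p under 0.01. Changes of at least 1.5-fold were 181 in striatum, 53 in cerebellum and 8783 between tissues. No filter gave 384 calls in striatum and 10 lists there, a filter of 6 gave 7 interaction calls, array weights gave 396 in cerebellum and 64 for the interaction. The cortex score as a covariate gave 27 in striatum and 2 for the interaction, and leaving out the arrays that stand apart (wild-type striatum 1 and wild-type cerebellum 4) 61 for the interaction; the cause was not tested. Htt in cerebellum moved from -0.27 to -0.17 with median centring. Gene lists called fell to 0 and 0 with an estimated correlation (camera in limma; 3933 and 2867 probe sets had an unadjusted p under 0.05) and to 2 in striatum and 1 in cerebellum with fry.

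With the replicate number as a block, 153 probe sets were called in striatum, 53 in cerebellum and 1 for the interaction, and 5 lists in cerebellum; it changed no other call count or list count beyond 1.5 times. Same-numbered arrays of the 2 genotypes correlated at -0.409 to -0.0881 in striatum and -0.423 to 0.119 in cerebellum, and 0 arrays correlated best with their own number in either tissue, but the near-equal means of the number sets make such values negative. Against the other numbers of its set, the own number averaged -0.234 and -0.234 in striatum and -0.139 and -0.112 in cerebellum (exact permutation p over 36 matchings 0.583 and 0.444), which gives no sign of pairing and does not exclude it. Leaving out 1 array gave 219 (without wild-type 4) to 689 (without wild-type 1) calls in striatum, 34 (without Q111 3) to 252 (without Q111 6) in cerebellum, 6 to 50 (without wild-type striatum 1) for the interaction and 14551 to 14924 between tissues. It gave 4 to 7 lists in striatum, 2 to 6 in cerebellum, and Htt differences of -0.0373 to 0.0423 in striatum and -0.323 to -0.231 in cerebellum. All other settings moved these counts by 1.5 times or less. Probe sets below the filter, near background, were not tested, and the number of arrays limits what smaller changes could be seen.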

Other observations

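The tests of vascular and clock genes in this part use lists fixed, or set out, before their values were seen; the choice to describe them, and Xist, was made after.

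Genes of blood vessels had low scores in both tissues of Q111 mice. The score of 13 endothelial and mural cell genes was 7.58 ± 0.06 log2 in Q111 striatum and 7.76 ± 0.11 in wild type, with 7.41 ± 0.04 and 7.55 ± 0.07 in cerebellum (SD, n = 6). All 6 Q111 arrays of each tissue lay below the wild-type mean. The exact permutation p was 0.00433 in each, and 0.165 and 0.0823 after adjustment over the lists, so neither passed that test. With fry the adjusted p was 0.0219 in striatum, which passed, and 0.103 in cerebellum. The camera adjusted p was 0.0685 in striatum (adjusted p = 0.707 with an estimated correlation) and 0.296 in cerebellum (adjusted p = 0.874 with an estimated correlation), and neither passed. The median log2 difference of the list went from -0.133 to -0.0814 with quantile normalisation and -0.0834 with median centring in striatum, and from -0.135 to -0.0591 and -0.0355 in cerebellum. The differences were -0.18 and -0.16 in numbers 1 to 3 and 4 to 6 of striatum and -0.18 and -0.08 in cerebellum. Cldn5, a tight junction gene of the blood-brain barrier, fell in striatum (-0.73, adjusted p = 5.99e-04) and differed by -0.42 in cerebellum (adjusted p = 0.0781), and the transporter gene Slco1a4 by -0.45 (adjusted p = 0.0721) and -0.49 (adjusted p = 0.106).

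Of 7 clock genes tested besides Per3 and Npas2, none passed in limma in either tissue; Bhlhe41, also set out for this test, was not measured past the filter. Per2 differed by -0.32 in striatum and -0.55 in cerebellum, Tef by -0.33 and -0.16, Ciart by -0.31 and -0.28, Dbp by -0.16 and -0.05, Arntl by -0.13 and -0.22, Nr1d1 by 0.37 and -0.12, and Nr1d2 by -0.01 and 0.01. The lowest adjusted p was 0.0725, for Tef in striatum.

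Xist, transcribed from the inactive X chromosome of females, had separate high and low levels in striatum and in replicate numbers 4 to 6 of cerebellum, but not in numbers 1 to 3 of cerebellum. In striatum it read 9.38, 3.52, 10.3, 4.09, 4.13 and 10.7 log2 in wild-type replicates 1 to 6 and 8.55, 3.52, 3.45, 10.97, 4.07 and 4.12 in Q111. In cerebellum replicates 4, 5 and 6 read 4.60, 4.52 and 11.4 in wild type and 10.2, 10.99 and 4.59 in Q111. Replicates 1, 2 and 3 read 7.26, 7.33 and 7.28 in wild type and 7.27, 7.34 and 7.32 in Q111. Another Xist probe set ran from 5.27 to 8.11 over these 6 arrays. Of the Y chromosome genes there, Eif2s3y read 6.10, 5.06 and 5.47 in wild type and 4.20, 4.08 and 4.09 in Q111, Kdm5d 5.09, 3.94 and 4.39 and then 2.98, 2.62 and 3.07, and Uty, in a probe set with the opposite order, 3.07, 3.02 and 4.25 and then 4.27, 4.145 and 4.44. Q111 replicate 5 was low in striatum and high in cerebellum. RNA pooled from both sexes, or a step that set the means of the number sets equal, would each place arrays between the high and low levels. RNA mixes before logs are taken, so a pool of equal parts alone would read near the high level, 10.2 to 11.4 in numbers 4 to 6. The 6 arrays at 7.26 to 7.34 lie well below that, which argues against equal pooling alone. A pool with a small female share, or pooling together with such a step, stays open. Xist in cerebellum averaged 7.30 in numbers 1 to 3 and 7.71 in numbers 4 to 6, so its deposited means are not equal, which goes against a step that leaves the means of all probe sets exactly equal and leaves a looser one open. If RNA was pooled, these 6 arrays are not single mice and their spread is not that between mice.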
